A study of Arabidopsis thaliana with 42 samples.

How the data were processed

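The series holds 42 libraries from immature inflorescence tissue of Arabidopsis thaliana. Of these, 14 are PATH libraries of RNA longer than siRNAs, in which Pol IV-dependent transcripts (P4RNAs) are read, 14 are small RNA libraries of the same genotypes, and 1 is an mRNA library of wild type. A separate set compares wild type with nrpb2, a weak mutant of the second-largest subunit of Pol II, by whole-genome bisulfite sequencing (4 libraries) and small RNA sequencing (4 libraries). The last pair, labelled RIP, is an AGO4 immunoprecipitate and its input from dcl2/3/4 plants. Libraries of Pol II chromatin immunoprecipitation (3 libraries) were not analysed here.

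The authors' library summary gives, per the file headers, whole numbers of all trimmed sequences and of uniquely mapped reads per library (other than per-feature values), and the deposited count of reads at Pol IV siRNA loci. Per the file headers, bad reads were removed and adapters trimmed. Reads were then mapped uniquely to TAIR10 with up to 3 mismatches for PATH, 0 for small RNA and 2 for mRNA. P4RNA there means reads of 27 nt and longer, and siRNA means 18 to 26 nt. A second table holds raw read counts, per the file headers, at 7632 Pol IV siRNA loci of 200 bp for 5 libraries, 1 each of wild-type and dcl2/3/4 PATH, wild-type and dcl2/3/4 small RNA, and wild-type mRNA. The deposited cytosine files hold counts of methylated and unmethylated reads for every cytosine. The deposited tag files hold counts of reads per distinct trimmed sequence. Tables of read length at Pol IV loci (nrpb2 set) and over a region set (RIP) are deposited counts too, and whether reads with several matches were kept is not stated in them. Per the submitters' processing notes, the build was TAIR10 and the tools were cutadapt 1.4 and TopHat. The aligner of the bisulfite reads is not given in the sources used here. No genome sequence was used here, so tags were not mapped.

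Because the locus table holds 1 library per genotype, the fits per locus that had been planned for P4RNA and siRNA were replaced by a test on the share of uniquely mapped reads at Pol IV loci in each library. Genotypes were grouped by label into wild type (3 libraries), dcl2/3/4 (2), mutants that keep other DICER-LIKE enzymes but lack DCL3 (dcl3, dcl2/3 and dcl3/4, 1 each) and mutants that lack Pol IV or RDR2 (nrpd1, nrp(d/e)2, rdr2, dcl3/nrpd1 and dcl3/rdr2, 1 each). Means of log2 shares were compared by two-sided exact permutation tests. Spread in the last pair of groups includes differences between genotypes. Replicate 1 of wild type and of dcl2/3/4 were the only PATH libraries sequenced paired-end, per the file headers. Values per locus were read as log2 of reads scaled to uniquely mapped reads (RPM) plus a pseudocount of 1, without a test. Shares of single libraries carry 95% exact binomial (Clopper-Pearson) intervals, which cover counting error only, since reads are not independent molecules. All p-values measure only the spread between these samples, since the files do not state whether replicates came from separate plants.

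Cytosines were used when every one of the 4 libraries had at least 4 reads. Levels are methylated reads over all reads, as the mean and SD of 2 libraries per group, and were compared by exact permutation, which with 2 against 2 cannot go below p = 0.3333. The chloroplast level stands for non-conversion. At each Pol IV locus with at least 10 usable cytosines of a context, summed methylated and unmethylated counts were tested with edgeR quasi-likelihood (glmQLFit and glmQLFTest, a term per library), two-sided, with Benjamini-Hochberg adjustment over loci and a threshold of 0.05. Genes were tested the same way, as were windows of 200 bp with at least 2% (CHH) or 5% (CG and CHG) methylation over all libraries. Genes were taken as the body with 1 kb on both sides, in place of upstream sequence alone, because the gene table gives no strand. Gene names came from a RefSeq table on TAIR10.1. A search for the T-loop pattern of cytosines and guanines at its set distance from the end of 625 tRNA genes found it in 62.9% at shift 0 and in at most 0.16% at any other shift up to 10 bp, so both assemblies were read as having the same coordinates. A name given with "near" is the closest gene to a locus between genes. Pericentromere bounds and gene lists (10 reporter genes of RNA-directed DNA methylation, 8 TAS genes, conserved miRNA families) were set before the data were examined, as were the comparisons, the tests and most alternatives. The miRNA families were not tested, since no mature miRNA sequences were used here. Tags of structural RNA, organelles and mRNA, listed beforehand too, were not counted, since tags were not mapped. Not every locus that met the naming rule is described.

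Tags of 23 and 24 nt, of any origin, were tested per sequence between nrpb2 and wild type by edgeR quasi-likelihood with the total of 18 to 28-nt tags as library size, no TMM, filterByExpr and the same adjustment. Shares by length were compared by exact permutation. The RIP pair has 1 library each, so its shares are given with binomial intervals and without a test.

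Named loci followed a fixed rule. Among loci past the threshold in which the libraries of both groups did not overlap, these were the 5 with the highest mean and the 5 with the largest change among those above the median, in each direction, and the 2 with the smallest p in the rarer direction. Every member of the gene lists was measured. In the locus table the rule was applied to values without a test. Loci with low CG methylation in wild type were singled out after their values were seen.

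Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. Uniquely mapped reads ran from 2351437 to 33934490 in PATH libraries and from 311690 to 16281060 in small RNA libraries, and were 14939094 in the mRNA library. In small RNA libraries of dcl3/nrpd1 and dcl3/rdr2 only 1.68% and 1.34% of sequences mapped uniquely. Mean coverage of nuclear cytosines was 20.2 to 21.4 reads, with 98.1% to 98.2% of them at 4 reads or more in each library. Replicate bisulfite libraries differed somewhat more than binomial sampling allows, with a chi-square per degree of freedom of 1.58 in wild type and 2.58 in nrpb2 for CG. For tags the same ratio was 25.7 and 22.8, far above sampling noise.

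Both model tests were checked on simulated data with changes planted in 200 loci or tags. With odds ratios of 2 and 4, CG recovered 7.0% and 66.0% of planted loci, CHG 86.0% and 98.0%, and CHH 24.0% and 93.0%. For tags, 2-fold, 4-fold and 16-fold changes were recovered in 1.47%, 21.2% and 83.3%. The adjustment depends on the share of changed features. Only 200 of 110658 tags were planted, while 28463 higher and 27564 lower were called in the data. These rates of recovery need not hold for the data. Among unchanged loci or tags 4.05% to 4.85% had an unadjusted p under 0.05. Alternatives covered the coverage minimum, the number of cytosines, limma and DESeq2, TMM, tag lengths, denominators, each replicate left out in turn and the replicate letter as a block.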

Results

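P4RNA was read in 14 PATH libraries and siRNA in 14 small RNA libraries of immature inflorescences, over wild type and 10 mutant genotypes. Wild type had 3 libraries of each kind and dcl2/3/4 had 2, while each other genotype had 1. Pol IV transcribes silenced DNA, RDR2 copies the transcripts into double strands, and the DICER-LIKE enzymes DCL2, DCL3 and DCL4 process these into siRNAs. Further libraries held wild-type mRNA (1), bisulfite-treated DNA of wild type and nrpb2 (2 each), small RNA of wild type and nrpb2 (2 each), and the AGO4 immunoprecipitate and input of dcl2/3/4 (1 each). The Pol IV loci of 200 bp lay 57.9% between genes, 23.1% in pseudogenes and 15.3% in protein-coding genes, and 58.7% of them were pericentromeric.

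Whether P4RNA builds up when dicing is lost was asked by comparing dcl2/3/4 with wild type. P4RNA at Pol IV loci was 54.6-fold higher in dcl2/3/4 as a ratio of geometric means, the form of every fold between groups of these libraries, with arithmetic means of 246554 ± 87665 RPM (reads scaled to uniquely mapped reads; SD, n = 2) against 5103 ± 2905 in wild type (SD, n = 3). As a share, 24.7% ± 8.77 of all mapped PATH reads of dcl2/3/4 lay at these loci and 0.510% ± 0.291 of those of wild type. Both dcl2/3/4 libraries, at 184566 and 308543, lay above the 3 wild-type libraries, which spanned 1878 to 7516. The two-sided exact permutation test gave p = 0.1, the smallest that 3 against 2 libraries allow, for a log2 change of 5.77. Replicate 1 of wild type and of dcl2/3/4 was sequenced paired-end and every other PATH library single-end, and in single-end libraries alone the log2 change was 5.53 (exact p = 0.3333). Without wild-type replicate 1, the lowest of its group, it was 5.16.

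Dependence of P4RNA on Pol IV and RDR2 was asked with mutants of either. P4RNA was 28.6-fold lower in nrpd1, nrp(d/e)2, rdr2, dcl3/nrpd1 and dcl3/rdr2, at 169.8 ± 89.0 RPM (SD, n = 5 genotypes), than in wild type (n = 3). NRPD1 is the largest subunit of Pol IV, and the second-largest subunit, lost in nrp(d/e)2, is shared with Pol V. The share was 0.0145% in nrpd1 (95% interval 0.0135 to 0.0155), 0.0202% in nrp(d/e)2 (0.0189 to 0.0215) and 0.0308% in rdr2 (0.0295 to 0.0322). Loss of DCL3 did not bring P4RNA back in these backgrounds, with 0.00876% in dcl3/nrpd1 (0.00814 to 0.00942) and 0.0106% in dcl3/rdr2 (0.01001 to 0.0112). The exact permutation test gave p = 0.0179, two-sided, the smallest of 56 splits, for a log2 change of -4.84. In single-end libraries alone the log2 change was -5.45 (exact p = 0.0476).

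Which DICER-LIKE enzyme limits P4RNA was asked with single and double mutants. P4RNA was 24.4-fold higher in the mutants that lacked DCL3 (109265 ± 28613 RPM, SD, n = 3 genotypes) than in wild type (n = 3). The fold over the geometric mean of wild type was 29.2 in dcl3, 28.4 in dcl2/3 and 17.5 in dcl3/4. In dcl2/4, where DCL3 is intact, P4RNA was at 5043 RPM (95% interval 4959 to 5129), 1.15-fold the geometric mean of wild type and inside the wild-type range. The log2 change of the DCL3 mutants was 4.61 (exact permutation p = 0.1, two-sided, the smallest of 20 splits) and 4.00 in single-end libraries alone.

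**Figure D1:**
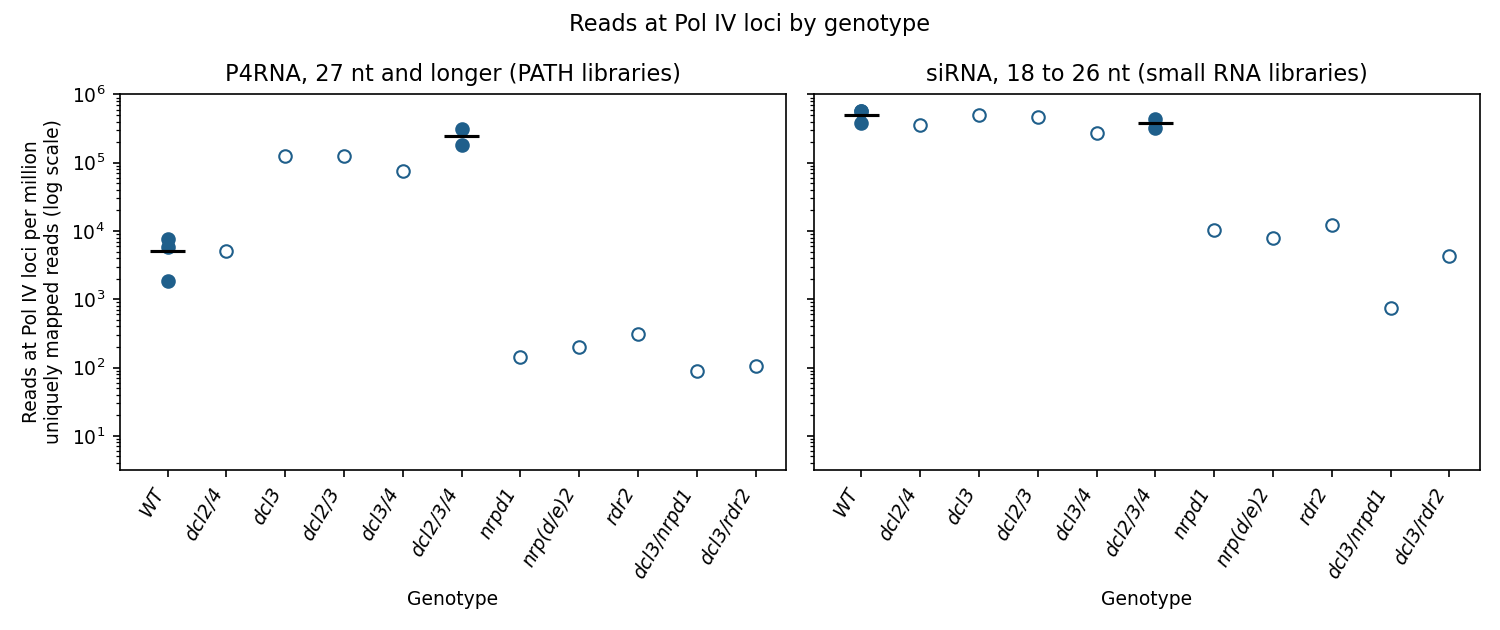
Reads at Pol IV loci in RPM (log axis) by genotype, for P4RNA (left) and siRNA (right). Filled points are libraries of genotypes with replicates, lines their means, and open points genotypes with 1 library. P4RNA was 54.6-fold higher in dcl2/3/4 than in wild type, and siRNA was 98.6-fold lower in Pol IV and RDR2 mutants (log2 -6.62, and -5.93 without dcl3/nrpd1).

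How siRNA depends on the same enzymes was asked in the small RNA libraries. In wild type 50.8% ± 11.1 of mapped reads were siRNAs at Pol IV loci (SD, n = 3). The mutants of Pol IV or RDR2 had 0.718% ± 0.468 (SD, n = 5 genotypes), which is 98.6-fold lower as a ratio of geometric means (log2 -6.62). The lowest share was 0.0742% in dcl3/nrpd1 (95% interval 0.0651 to 0.0842), 672-fold below the geometric mean of wild type, in a library of which 1.68% mapped uniquely. Without that library the log2 change of the group was -5.93, and with shares of all sequences it was -9.15, so the size of the fold depended on this library and on the scaling. The nrpd1, nrp(d/e)2 and rdr2 single-gene mutants held 1.05% (1.04 to 1.06), 0.803% (0.788 to 0.818) and 1.23% (1.22 to 1.24), and dcl3/rdr2 held 0.431% (0.408 to 0.454). The exact permutation test gave p = 0.0179, two-sided, the smallest of 56 splits.

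Loss of the DICER-LIKE enzymes left a large share of siRNA reads at Pol IV loci. The share was 37.9% ± 7.33 in dcl2/3/4 (SD, n = 2; log2 -0.41, exact permutation p = 0.3, where 0.1 is the smallest possible). In dcl3, dcl2/3 and dcl3/4 it was 41.5% ± 12.5 (SD, n = 3 genotypes; log2 -0.32, exact permutation p = 0.5, where 0.1 is the smallest possible). In both comparisons the ranges of the libraries overlapped. Leaving out 1 library gave log2 changes of -0.61 to -0.21 for dcl2/3/4 and of -0.51 to -0.0364 for the DCL3 mutants, the smallest without dcl3/4. With shares of all sequences the log2 changes were -0.71 for dcl2/3/4 and -0.53 for the DCL3 mutants. For replicate 1 the counts per locus summed to 31.5% in dcl2/3/4 and 60.7% in wild type, against 43.1% and 56.3% here. The size of the change in dcl2/3/4 thus depended on the source of the counts. The single values were 49.8% in dcl3 (49.8 to 49.9), 47.5% in dcl2/3 (47.5 to 47.5), 27.1% in dcl3/4 (27.0 to 27.1) and 35.7% in dcl2/4 (35.6 to 35.7).

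Where P4RNA built up was read from 1 library per genotype, without a test and with no error. P4RNA was higher in dcl2/3/4 at 7521 loci and lower at 66, with a median log2 change of 1.77 on the scale of RPM plus 1. The most abundant locus lay near PYL10, an abscisic acid receptor gene (chromosome 4, 13902795 to 13902995, build TAIR10), with 1371 P4RNA reads in wild type and 87217 in dcl2/3/4, 90.8-fold on that scale. A locus in AT4G08545 (chromosome 4, 5439004 to 5439204) had 820 and 81463 reads (140-fold), and a locus in the transcribed pseudogene AT3G43832 (chromosome 3, 15682414 to 15682614) had 798 and 76323 (134-fold). The highest fold, 153, was near RECQSIM, a RecQ helicase-like gene (chromosome 5, 9801198 to 9801398). The locus in the long non-coding RNA gene AT4G05995 (chromosome 4, 7592404 to 7592604) had 540 and 49846 reads. None of these loci had a read in the mRNA library, in which 11.9% of all loci had any.

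The siRNA reads of the same pair of genotypes went the other way, lower in dcl2/3/4 at 7008 loci and higher at 615 (median log2 change -1.11). Near the pseudogene AT4G07031 (chromosome 4, 4105004 to 4105204) they were 43457 in wild type and 2646 in dcl2/3/4, 8.79-fold lower. In AT2G21100 (chromosome 2, 9048320 to 9048520) siRNA was 3.25-fold higher, with 188 and 336 reads. A large siRNA deficit spanned 4 adjacent loci over the gene AT1G49260 (chromosome 1, 18225933 to 18226733), with 33251 reads in wild type and 81 in dcl2/3/4, 220-fold lower after scaling to mapped reads. P4RNA at these 4 loci was also lower, with 493 and 36 reads (9.36-fold), and in the bisulfite set wild type had only 1.63% ± 0.906 CG methylation at the most siRNA-rich of them. Near NLP1, a nitrilase-like gene (chromosome 2, 11739923 to 11740123), 1712 siRNA reads stood against 1. The locus table summed to 60.7% and 31.5% of mapped siRNA reads in wild type and dcl2/3/4, against 56.3% and 43.1% for the same libraries in the library summary, a discrepancy of the tables that was not resolved.

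Whether loci with more siRNA in wild type also gave more P4RNA without dicing was asked by correlation across loci, which are not independent replicates. Wild-type siRNA and dcl2/3/4 P4RNA had a Spearman rho of 0.777 and a Pearson r of 0.820 on the log2 scale. In the pericentromere rho was 0.828 and on the arms 0.732. Reads of siRNA length in dcl2/3/4 had a rho of 0.890 with dcl2/3/4 P4RNA and of 0.841 with wild-type siRNA. Wild-type mRNA had a rho of -0.03 with dcl2/3/4 P4RNA and of -0.02 with wild-type siRNA. Only 911 loci, 11.9%, had any mRNA read, so most mRNA ranks were tied and these values cannot show whether a relation exists. No p was computed, since neighbouring loci are not independent.

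Reporter genes of RNA-directed DNA methylation with a Pol IV locus in the gene or within 1 kb of it were SDC, QQS, MRD1, AtMu1 and APOLO, 5 of 10. Their P4RNA reads in wild type and dcl2/3/4 were 0 and 58 at SDC, an F-box gene, 7 and 65 at QQS, an orphan gene of starch metabolism, 1 and 109 at MRD1, 0 and 184 at the Mutator-like element AtMu1, and 0 and 36 at the non-coding gene APOLO. Their siRNA reads were 85 and 25, 52 and 26, 104 and 31, 279 and 74, and 35 and 12, in that order, from libraries of unequal depth. Scaled to mapped reads they were 12.3 and 6.73, 7.50 and 7.00, 15.0 and 8.35, 40.3 and 19.9, and 5.05 and 3.23 RPM, so QQS was nearly unchanged. Of the 8 TAS genes, precursors of trans-acting siRNAs, only TAS3C had a Pol IV locus, with 8 and 178 P4RNA reads and 1183 and 213 siRNA reads. Scaled to mapped reads its siRNA was 170.7 and 57.4 RPM.

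Whether Pol II takes part in methylation of Pol IV loci was asked by comparing nrpb2 with wild type. CHH methylation fell at 538 of 7629 Pol IV loci in nrpb2 and rose at 38 (edgeR, n = 2 against 2), and by limma at 336 and 12 of the same loci. Near AT1G60110 (chromosome 1, 22167736 to 22167936) it went from 18.9% ± 3.12 to 0.307% ± 0.085 (adjusted p = 8.69e-06 by edgeR), close to the CHH level of the chloroplast, 0.275% in wild type. Near AT4G11790 (chromosome 4, 7090007 to 7090207) it went from 15.4% ± 0.496 to 0.583% ± 0.367, and near ABCG11, a transporter gene for cuticle lipids (chromosome 1, 6141408 to 6141608), from 14.1% ± 1.36 to 0.586% ± 0.303. Loci near PAB4, which encodes a poly(A)-binding protein, and near the ubiquitin ligase gene CNI1 fell to 0.993% ± 0.919 and 1.61% ± 1.38 from 11.9% ± 1.15 and 13.0% ± 0.064. Among loci with the highest CHH levels, one near MAG1 (chromosome 3, 17640416 to 17640616) fell from 19.5% ± 0.313 to 8.92% ± 0.525. The gains with the smallest p were in AT1G14780, from 0.257% ± 0.058 to 7.60% ± 2.25, and AT1G50350, from 2.66% ± 0.862 to 9.20% ± 0.181. On the arms 345 of 3150 loci fell, 11.0%, and in the pericentromere 193 of 4479, 4.31%. Among windows tested in the same way over the genome, CHH fell in 721 and rose in 72 of 11265 over Pol IV loci, and in 2147 and 343 of 100051 elsewhere. Without nrpb2 replicate b the number of gains was 68. Of 2540 loci tested in all 3 contexts, 138 lost CHH. Of these, 125 also lost CHG and 114 also lost CG, where independence would give 15.0 and 15.4.

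CHG methylation fell at 392 of 3714 Pol IV loci and rose at 44. Among falls above the median level in which the libraries of both groups did not overlap, the largest in odds were near AT1G31163 (chromosome 1, 11127020 to 11127220), from 72.6% ± 2.04 to 37.9% ± 19.9, and in AT4G20735 (chromosome 4, 11123790 to 11123990), from 73.2% ± 2.42 to 42.9% ± 5.90 (adjusted p = 1.58e-05 by edgeR). In PPME1, a pectin methylesterase gene (chromosome 1, 26344138 to 26344338), it fell from 76.2% ± 3.22 to 54.0% ± 9.91, and near XPB1, a TFIIH helicase gene, from 69.9% ± 4.27 to 46.1% ± 8.19. The P4RNA-rich locus in AT4G05995 fell from 80.8% ± 1.23 to 72.5% ± 3.21. Gains with the smallest p were near AT3G44570, from 28.8% ± 1.04 to 68.3% ± 3.57, and near AT3G58415, from 34.5% ± 2.13 to 60.7% ± 0.840. In windows over Pol IV loci CHG fell in 526 and rose in 60 of 5340, and elsewhere in 2121 and 515 of 45716. Losses of over 20 points numbered 208 and gains of that size 5. Without wild-type replicate a or b the number of gains was 11 or 13.

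CG methylation fell at 561 of 4254 Pol IV loci and rose at 49. By more than 20 points it fell at 352 loci and rose at 7. The median tested locus had 91.3% CG in wild type, so most loci could not gain over 20 points. Losses of CG were no more frequent in windows over Pol IV loci (890 of 6240, 14.3%) than elsewhere (14714 of 90977, 16.2%). Gains were fewer, 100 (1.60%) against 9779 (10.7%), in windows not matched for CG level. Among windows at 80% to 100% wild-type CG with at least 20% CHG, 0 gained over 20 points, over Pol IV loci or elsewhere. Losses were named only among loci above the median CG level, so none of the 352 loci that lost over 20 points is named. In the non-coding gene AT2G05695 (chromosome 2, 5009519 to 5009719) CG fell from 97.4% ± 0.443 to 86.7% ± 3.04, and near EMB93 (chromosome 2, 899002 to 899202) from 96.3% ± 1.30 to 86.0% ± 3.14. The gains with the smallest p were near CHLI2, a subunit gene of magnesium chelatase (chromosome 5, 18627574 to 18627774), from 18.6% ± 2.498 to 60.4% ± 2.74 (adjusted p = 3.38e-15 by edgeR), and in AT1G49260, from 3.76% ± 1.34 to 26.4% ± 6.08. CG also rose near CRY2, a blue-light receptor gene, from 90.4% ± 0.620 to 96.1% ± 0.375. Pseudogenes lost CG at 5.30% of their loci, protein-coding genes at 18.5% and loci between genes at 15.2%. Loci that lost CG had a median wild-type siRNA level of 36.6 RPM, loci that gained it 26.3 and loci without a call 15.7, and the rho of siRNA with the CG change was -0.12 over all loci. Of 2540 loci tested in all 3 contexts, 195 lost CG and CHG together, where independence would give 30.9. Without wild-type replicate a or b the number of gains was 20 or 26.

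**Figure D2:**
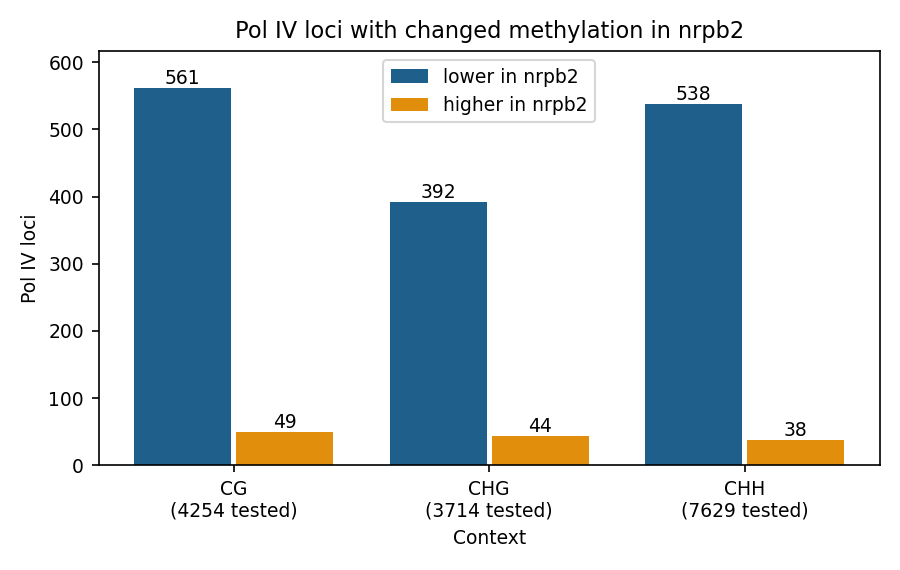
Pol IV loci with lower or higher methylation in nrpb2 than in wild type at an adjusted p under 0.05 (edgeR), by cytosine context, with the number tested under each. Losses outnumbered gains in every context, 561 to 49 for CG, 392 to 44 for CHG and 538 to 38 for CHH. Wild-type CG was already 91.3% at the median tested locus, which limited gains of CG. In windows outside Pol IV loci losses also outnumbered gains, 14714 to 9779, 2121 to 515 and 2147 to 343.

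Summed over Pol IV loci, nrpb2 had lower methylation in every context, with differences above the spread between replicates. CG was 85.7% ± 0.376 in wild type and 80.9% ± 0.970 in nrpb2 (SD, n = 2 each), CHG 50.2% ± 0.882 and 47.5% ± 0.421, and CHH 7.19% ± 0.0527 and 6.41% ± 0.170. Loci on the arms differed most, with CG at 80.3% ± 0.597 and 71.9% ± 0.866, against 89.1% ± 0.260 and 86.3% ± 0.944 for pericentromeric loci. Protein-coding genes had 15.5% ± 0.0310 and 15.7% ± 0.0996 CG, pseudogenes 81.9% ± 0.287 and 82.0% ± 0.932, and the nuclear genome 23.3% ± 0.0145 and 24.1% ± 0.481. The direction of CG over genes, pseudogenes and the genome depended on how cytosines were weighted. CHH was also lower in pseudogenes, at 6.40% ± 0.0162 and 5.87% ± 0.0434, and over the pericentromere, at 3.48% ± 0.00928 and 3.28% ± 0.0446. In windows with at least 2% CHH methylation the median difference was -0.567 points over Pol IV loci and -0.547 elsewhere. Over the nuclear genome outside Pol IV loci the CHH level differed by 0.0139 points, against -0.776 at Pol IV loci, but the sign outside them was not stable, with -0.0909 as the mean of per-cytosine fractions and -0.0106 with the chloroplast level subtracted. The CHG deficit at Pol IV loci came from a part of them. The median locus differed by -0.104 points, with 1895 loci lower and 1819 higher, and the pericentromeric median was 0.272. The CG deficit was uneven too, with a median of -0.535 points against a mean of -4.61, and 2427 tested loci lower and 1827 higher. Exact permutation gave p = 0.3333 for each Pol IV difference, the smallest that 2 against 2 libraries allow, two-sided. On the unmethylated chloroplast CG read 0.321% ± 0.0206 and 0.366% ± 0.0185.

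**Figure D3:**
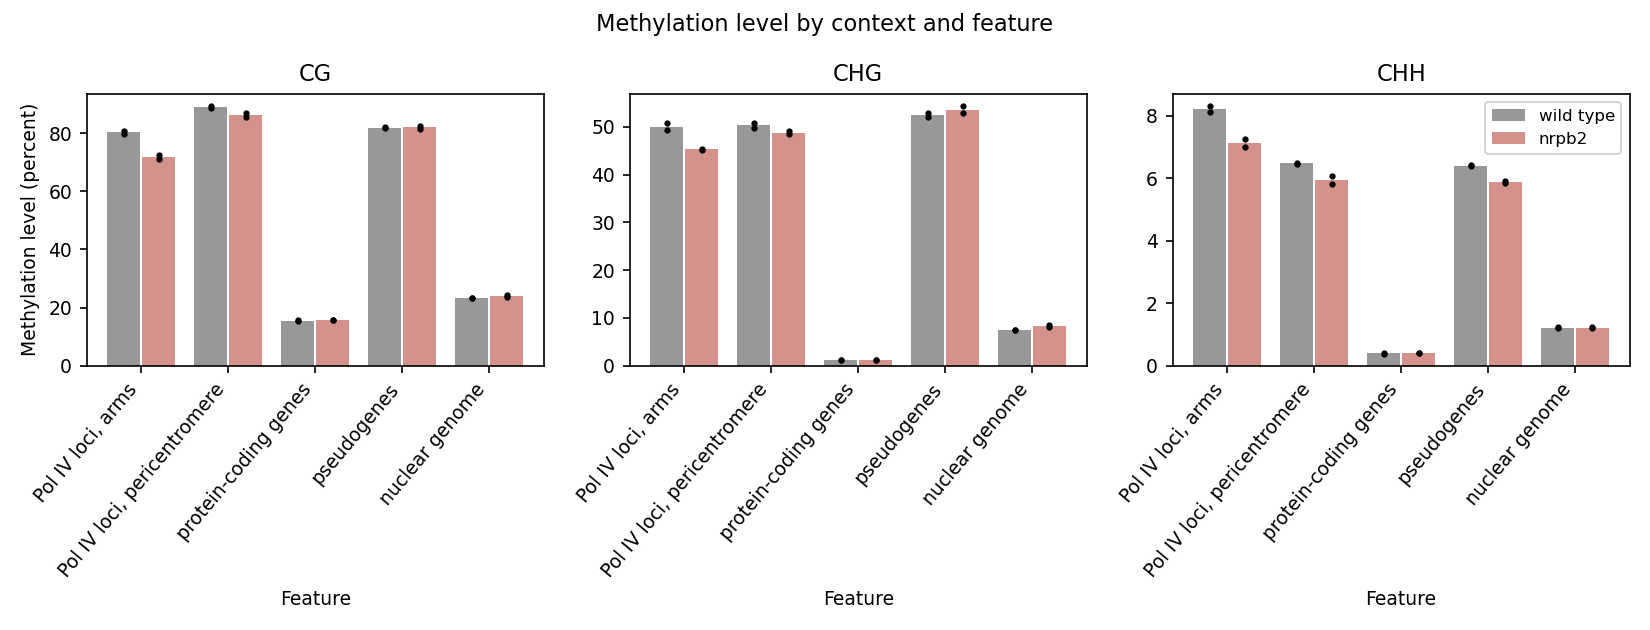
Methylation level in percent (methylated reads over all reads) by feature in wild type and nrpb2, for CG, CHG and CHH, each on its own axis from 0. Bars are means of 2 libraries and points the libraries. CG at Pol IV loci on the arms was 80.3% in wild type and 71.9% in nrpb2.

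Among the 10 reporter genes, CG over the gene with 1 kb on both sides fell in 6 and rose in 0, adjusted over all 37862 genes, and in 6 adjusted over the list alone. QQS fell from 61.2% ± 1.404 to 44.1% ± 1.38 (adjusted p = 3.92e-05 by edgeR), FWA, a homeodomain gene silenced by repeats, from 26.5% ± 1.2 to 21.2% ± 0.130, and MEA, an imprinted Polycomb gene, from 9.24% ± 0.013 to 5.83% ± 0.270. ROS1, a DNA demethylase gene, IBM1, a histone demethylase gene, and EPF2, which encodes a peptide that limits stomata, were the others, EPF2 from 1.05% ± 0.059 to 0.288% ± 0.069. That last level is below the chloroplast CG level of nrpb2, 0.366%. SDC, MRD1, AtMu1 and APOLO did not pass, with 19.8% and 19.1%, 37.1% and 34.8%, 91.5% and 91.5%, and 47.4% and 50.01%. Each of these has a Pol IV locus in the gene or within 1 kb. Of the genes in which CG fell only QQS has one, so the falls did not follow the presence of a Pol IV locus. CHG fell in QQS, from 27.6% ± 0.436 to 19.9% ± 0.383, and in IBM1, 2 of 10, also 2 adjusted over the list alone. CHH fell in 0, or in 1 (SDC) adjusted over the list alone, at 1.42% ± 0.005 and 1.101% ± 0.020. Of the 8 TAS genes, CG fell in TAS3A, from 6.65% ± 0.277 to 1.08% ± 0.281, in TAS2 and in TAS3C, 3 also adjusted over the list alone. CHG and CHH fell in TAS3A, 1 each by either adjustment. Over all genes CG fell in 7569 and rose in 4161.

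How siRNA lengths changed in nrpb2 was asked from reads at Pol IV loci by length. Reads of 23 nt made up 4.94% ± 0.231 of 18 to 28-nt reads at Pol IV loci in wild type and 10.2% ± 0.643 in nrpb2 (SD, n = 2 each). Reads of 24 nt, the main product of DCL3, made up 76.7% ± 0.227 and 74.0% ± 1.22. The ratio of 23-nt to 24-nt reads was 0.0645 ± 0.00320 and 0.138 ± 0.0109, 2.13-fold higher in nrpb2. Scaled to 18 to 28-nt tags, 24-nt reads at Pol IV loci were 190023 ± 1021 RPM in wild type and 151265 ± 11144 RPM in nrpb2. Over all 24-nt tags, of any origin, those starting with A made up 67.2% ± 0.0947 and 58.9% ± 0.00765, and those starting with G 7.67% ± 0.0626 and 14.5% ± 0.753. Each of these differences exceeded the spread between replicates (exact permutation p = 0.3333, the smallest possible). Wild-type libraries held 32.5% ± 0.295 tags of 14 to 16 nt and nrpb2 libraries 7.19% ± 3.56, and with tags of all lengths as the denominator the log2 change of 24-nt reads at Pol IV loci was 0.37, higher in nrpb2, in place of -0.33.

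**Figure D4:**
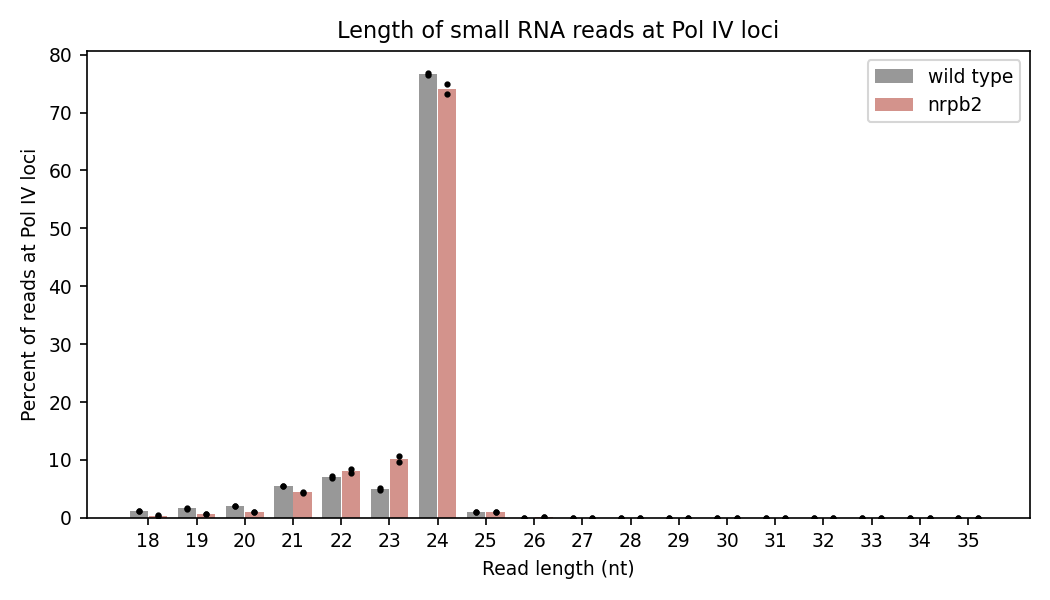
Share of small RNA reads at Pol IV loci by length (nt) in wild type and nrpb2, in percent of reads of the lengths drawn. Bars are means of 2 libraries and points the libraries. The 23-nt share was 2.06-fold higher in nrpb2, while 24-nt reads remained the main class in both.

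Sequence by sequence, 28463 of 110658 tags of 23 and 24 nt rose in nrpb2 and 27564 fell (edgeR, n = 2 against 2). Of the 23-nt tags 10254 of 17426 rose and 2549 fell, and of the 24-nt tags 18209 of 93232 rose and 25015 fell. Among 24-nt tags, 47.7% of those starting with G rose, against 12.8% of those starting with A. The files do not pair tags with genes, and the tags are of any origin, so those counted and named here need not be siRNAs. Some of the most abundant that rose and fell are given by sequence. AACGACTCTCGGCAACGGATATC went from 714.5 ± 66.3 to 2780.3 ± 604 RPM and GGCTGTCAGCGGACTGCTCGAGC from 5.42 ± 1.74 to 1056 ± 693. CCTAACAGACCGGTAGACTTGAAC went from 9337 ± 141 to 3932 ± 742 and TTGAAGAGGACTTGGAACTTCGAT from 1182 ± 321 to 156.1 ± 11.3. With TMM scaling 30899 tags rose and 22837 fell, so the split depended on the scaling. Without wild-type replicate a or b the number that fell was 12248 or 10061.

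What AGO4, the Argonaute that binds 24-nt siRNAs, holds when dicing is lost was asked by comparing its immunoprecipitate from dcl2/3/4 with the input, 1 library each. Of reads of 20 to 40 nt over the region set of the table, those of 22 to 24 nt made up 54.1% (95% interval 53.7 to 54.5) in the immunoprecipitate and 5.68% (5.47 to 5.90) in the input, 9.52-fold more. Reads of 24 nt alone made up 21.0% (20.7 to 21.3) and 1.85% (1.73 to 1.98), 11.3-fold more. Reads of 27 to 40 nt, the length of P4RNA, made up 17.2% (16.9 to 17.5) and 80.2% (79.9 to 80.6). Over all tags in place of the region set the log2 ratio of 27 to 40-nt reads was -0.25 in place of -2.22, and that of 22 to 24-nt reads 2.44 in place of 3.25. Of all 24-nt tags, 55.8% (55.4 to 56.2) of the immunoprecipitate and 25.2% (24.5 to 26.0) of the input started with A. The region set of this table is not fully named in its title and held 68784 of 15787296 reads of the immunoprecipitate and 46408 of 7862784 of the input, and no test between conditions was possible with 1 library each.

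**Figure D5:**
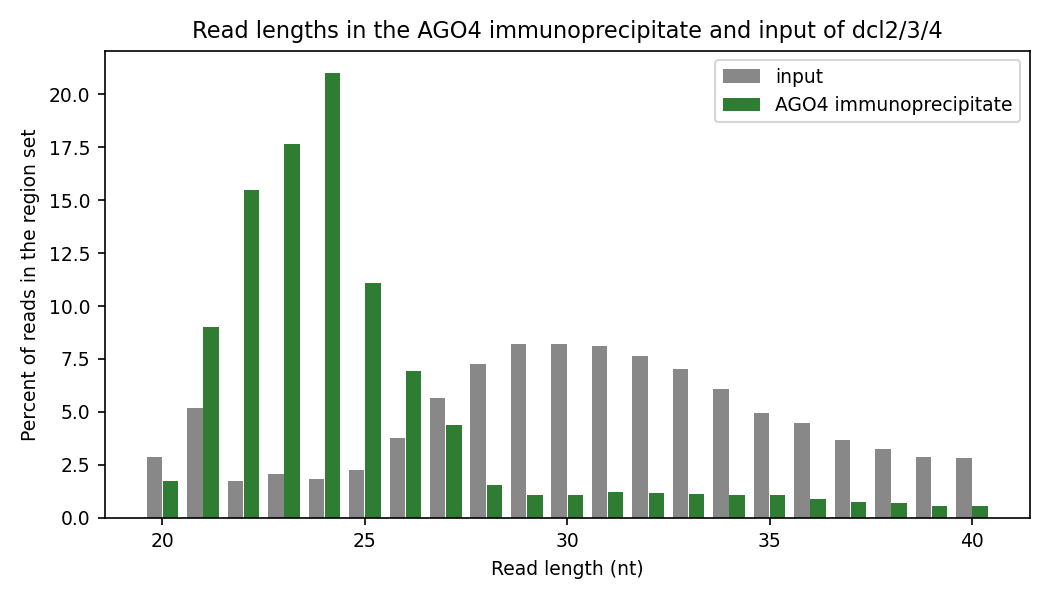
Share of reads by length (nt) over the region set in the AGO4 immunoprecipitate and the input of dcl2/3/4, in percent of reads of 20 to 40 nt, 1 library each. The immunoprecipitate peaked at 24 nt (21.0%), and 80.2% of the input was 27 to 40 nt long.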

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

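All tests in this part were chosen after the results were seen. In wild type 6.31% of CG reads assigned to the mitochondrion read as methylated, far above the chloroplast. Whether these reads came from the organelle was not tested. Tags of 14 to 16 nt made up 32.5% of reads in wild-type libraries of the nrpb2 set. The most abundant sequence of the AGO4 library, of 18 nt, made up 60.8% of its reads, and that of the input, also of 18 nt, 38.3%, and their source was not tested.

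The rise of 23-nt over 24-nt reads at Pol IV loci in nrpb2 was weighed against handling of the RNA. A shift in size selection would place the 23-nt ratio between those of its neighbours, but it was 2.059 while 22 nt stood at 1.156 and 24 nt at 0.966. Selection of longer RNA may still have added to the fall at 18 nt (0.3245) and the rise at 28 nt (4.481). Trimming at the 3′ end was weighed with 23-nt tags, of any origin, that lack the 5′ base of a 24-nt tag. These were at least 2.267-fold higher per 24-nt tag with sets of 24-nt tags from wild-type libraries. With sets from nrpb2 libraries they were at least 1.90-fold higher. Such a tag can also be a 24-nt tag that starts at the next base and lacks its 3′ base. Trimming at the 3′ end alone therefore remains open. Breakdown from both ends remains open, since 22-nt reads gained as a share of reads at Pol IV loci (1.156) but were no higher when scaled to 18 to 28-nt tags (log2 -0.0729), while the shares of 18 to 21 nt fell, and a difference in RNA state between the genotypes cannot be told apart from the mutation with these libraries. Altered dicing in nrpb2 is a hypothesis that was not tested.

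The loss of CG methylation at Pol IV loci in nrpb2 may be technical, inherited or due to the mutation. The chloroplast CG level, which stands for non-conversion, differed by only 0.04443 points, with nrpb2 the higher. This argues against poor conversion in wild type. Drift at the rate of other windows of like wild-type CG level and at least 20% CHG would give a ratio near 1. Windows over Pol IV loci lost over 20 points 3.226 times as often as these, from 2.41 to 4.82 times by chromosome. Called losses of any size were no more frequent than in all other windows (14.3% against 16.2%). The windows were not matched for CHG level above that minimum or for place. Called CG losses were 21.3% of Pol IV loci on the arms and 8.18% in the pericentromere, so drift at a rate that differs by place remains open. Inherited methylation in the nrpb2 line remains open and cannot be told apart from the mutation, since at least 2093 of 38714 windows with little CHG methylation outside Pol IV loci differed by over 30 points in each pair of wild-type and nrpb2 libraries, in both directions, and at most 1 did between replicates. Losses of CHH share this limit, since 114 of the 138 loci that lost CHH among those tested in all 3 contexts also lost CG.

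The deficit of both RNA classes over AT1G49260 in dcl2/3/4 was weighed against other changes in the line. A need for the DICER-LIKE enzymes for siRNA but not for P4RNA remains open, since lower P4RNA at 4 of the 4 loci is part of the pattern itself and rests on 1 library per genotype, while all 15 neighbouring loci within 100 kb had higher P4RNA. Sequence lost or altered in the dcl2/3/4 line remains open, since 22.05% of the 195 loci with over 16-fold lower siRNA (43 loci) also had lower P4RNA, against 0.865% of all loci (66). A candidate explanation is siRNA and methylation at such loci that some wild-type plants carry and other lines lack, since other loci with over 16-fold lower siRNA had under 10% CG in the bisulfite wild type 12.81 times as often (18 of 78) as loci with at least 142 siRNA reads, their lowest (34 of 1887), and 11.1 times as often as other loci of like siRNA reads. This was found and tested on the same data, and siRNA at such loci may instead depend more on dicing.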

How the results depend on the processing

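Alternatives were run for 45 results, and those chosen after seeing the data were shares of all sequences, single-end libraries alone, tags of all lengths or of 20 to 25 nt as denominator, the filter of 10 reads over 4 libraries, and for RIP all tags, all 20 to 40-nt tags, and all tags in place of the region set. Of the alternative values 244 kept their direction, their count within 1.5-fold or their value within the spread between libraries, 55 moved and 20 changed direction. For methylation levels and for shares in DICER-LIKE mutants direction alone was judged, since the exact p could not pass 0.05, and sizes could differ. All 49 for library shares kept direction. With replicates 1 and 2 as a block (pairing by number), P4RNA in dcl2/3/4 had a log2 change of 5.99 and siRNA -0.60 (exact p = 0.5 each). Replicate letters share only a name, since deviations of the same letter had correlations of 0.002 (CHH), -0.007 (CHG), -0.006 (CG) and 0.013 (tags). With letters as a block CHG gains were 71 and tags 28062 higher and 26783 lower. The cause was not tested for any value below unless stated. The relation across loci was r = 0.800 with a pseudocount of 0.1, rho 0.732 and r 0.793 on the arms, and rho 0.828 and r 0.854 in the pericentromere. By limma CHH gains were 12 and losses 336, and CHG gains 22. At 10 reads per cytosine CHG gains were 26. With 5 cytosines CHG gains were 67 and losses 779, and CG losses 853, as more loci were tested. Leaving out 1 library gave CHH gains of 39 to 68, CHG gains of 11 to 57 and CG gains of 20 to 57. As means of per-cytosine fractions the change in points was -0.392 (CG), -0.0211 (CHG) in protein-coding genes, -0.504 (CG) in pseudogenes and -0.753 (CG), -0.130 (CHG) and -0.0982 (CHH) over the genome. With the chloroplast level subtracted CHH was -0.00864 in protein-coding genes and -0.0149 over the genome. Leaving out 1 library gave -0.541 to 0.777 for CG in pseudogenes and -0.00769 to 0.0268 for CHH over the genome. Against tags of all lengths the log2 changes for 21, 22, 23 and 24 nt were 0.43, 0.59, 1.60 and 0.52 over all tags and 0.12, 0.63, 1.46 and 0.37 at Pol IV loci, since short tags differ between the groups. Against 20 to 25-nt tags they were -0.0162 (22 nt), 0.99 (23 nt) and -0.0835 (24 nt) over all tags, and -0.49, 0.0208, 0.85 and -0.23 at Pol IV loci. By distinct sequences they were 0.18 (22 nt) and 0.53 (23 nt). Leaving out 1 library gave -0.44 to -0.0689 (21 nt), -0.17 to -0.0415 (22 nt), 0.83 to 0.98 (23 nt) and -0.21 to -0.14 (24 nt) over all tags, and -0.61 to -0.55, -0.0926 to -0.0530, 0.72 to 0.81 and -0.41 to -0.26 at Pol IV loci. DESeq2 called 14421 tags lower. Restricting to 24 nt gave 17896 higher, all of 18 to 28 nt 59650 higher and 42710 lower, and the filter of 10 reads 56290 higher. Leaving out 1 library gave 10061 to 27863 lower, the least without wild-type replicate b. With TMM 30899 were higher and 22837 lower. For AGO4 over input the log2 ratio of 22 to 24-nt reads was 2.81, 4.44, 2.44 and 2.06, and that of 27 to 40-nt reads -2.66, -1.04, -0.25 and -0.96, against all tags, against 20 to 40-nt tags, over all tags in place of the region set, and by distinct sequences. Not run were fits per locus for P4RNA and siRNA with their pseudocounts, low-value filters, TMM or centring, limma or DESeq2 and joint fit of genotypes (1 library per genotype in the locus table), values per kb (all loci are 200 bp), weighting of tags with several matches, miRNA results and library sizes, denominators without structural RNA, and tags with at least 1 count. Depth limits P4RNA per locus in wild type, with a median of 2 reads.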

Other observations

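Some Pol IV loci rich in siRNA were almost unmethylated in the bisulfite wild type, a set of loci chosen after their values were seen. CG was under 10% in wild type at 67 of 4254 loci, and these had a median of 925 wild-type siRNA reads, against 117 at the others. Near AT5G19165 (chromosome 5, 6440399 to 6440599) 12023 siRNA reads stood beside 1.67% ± 0.872 CG methylation (n = 2), near ML2, a gene of the MEI2-like RNA-binding family (chromosome 2, 17848324 to 17848524), 10397 reads beside 3.07% ± 0.442, and near AT3G50030 (chromosome 3, 18545818 to 18546018) 9676 reads beside 4.18% ± 1.87. P4RNA was higher in dcl2/3/4 at 58 of the 67, which include the 4 over AT1G49260, and at 4158 of the other 4187. The small RNA and bisulfite libraries of wild type are separate samples, and whether they share a seed stock is not stated.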
